A study of Caenorhabditis elegans with 15 samples.

How the data were processed

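The series holds 15 libraries of whole adult C. elegans, 3 for each of 5 genotypes, which the labels' protocols describe as TRIzol-extracted RNA made into libraries with an mRNA kit; WT, fbf-2 and 3xlnc are labelled total RNA and fbf-1 and fbf-1 3xlnc polyA RNA. Per the labels, the authors used STAR 2.7.9a, featureCounts with Subread 2.0.1, DESeq2 1.34.0 and the genome build WBcel235, with no settings stated. The annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here, so genes with near-identical copies (major sperm protein, vitellogenin and hsp-16 genes, fbf-1 and fbf-2) and antisense pairs are uncertain to the degree that counting split or merged their reads.

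The authors deposited 3 tables, 1 per comparison, over the same 46904 gene identifiers. Columns of raw counts per gene are whole numbers as the authors' counting gave them, per the file headers, and the WT counts are identical in the 2 tables that hold them. The authors' deposited table also gives log2 fold changes and adjusted p-values, with flags for germline-enriched and FBF-2-bound genes whose definition is not given in the sources used here. Its padj column calls 1303 genes up and 1359 down in fbf-2, 1290 and 494 in 3xlnc, and 1223 and 1058 in fbf-1 3xlnc at an adjusted p under 0.05. It leaves the targeted genes without a fold change (fbf-2, the 3 linc genes, and fbf-1 with the 3 linc genes). A further 18 columns of normalised per-sample values were not used.

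Columns were matched to samples by name. The fbf-1 3xlnc columns could be matched to the group but not to single samples, because their numbers fit the title of one sample and the library name of another, so their numbers here only tell libraries apart. Gene identifiers were matched to the WBcel235 annotation, release 115 (46817 of 46904 found), which gave positions.

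All tests started from the raw counts. In R 4.3.3, edgeR 4.0.16 applied filterByExpr, TMM scaling, dispersion estimation and the quasi-likelihood F test (glmQLFit, glmQLFTest) to the 6 libraries of each comparison, with no replicate block and Benjamini-Hochberg adjustment over all genes tested; an adjusted p under 0.05 counts as changed. Fold changes are mutant over control, SE is that of the log2 fold change, and levels are CPM of the total counts with SD over 3 libraries. The difference between backgrounds was the interaction contrast over 12 libraries. Gene lists, 27 in number and 26 of them tested as lists, were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. A list needed 5 tested members. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison; no fixed list passed in any comparison when the correlation was estimated, and fry, which asks whether a list's genes move on balance in 1 direction and not whether they differ from other genes, passed 9, 7 and 5. The named genes are the targeted genes, the 8 largest rises and 8 largest falls with an adjusted p under 0.05, a mean of 50 counts and no overlap between groups, and the 3 members with the smallest adjusted p of each passing list and of the FBF target, stem cell, meiotic, sex determination and oocyte lists; the text names those and no others, except the chaperones in the closing section and genes chosen after their values were seen, where so stated. Of genes tested, 39.7%, 33.6% and 38.9% had no overlap between groups in the 3 comparisons, where chance gives 10%.

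Counts were simulated with 200 genes changed, from the control means, the real library sizes and spreads fitted over mutant and control libraries together. For the interaction the means were over all 12 libraries, and only fbf-1 3xlnc held changes. The fbf-2 procedure found 24, 74.5, 95.7 and 100% of genes changed 1.5-, 2-, 4- and 8-fold among 13112 tested. The 3xlnc procedure found 27.7, 58.7, 93.8 and 100% among 13234, and the fbf-1 3xlnc procedure 56.2, 82, 95.7 and 98% among 13747. The interaction found 20, 52.1, 83.7 and 90% among 14540. Unchanged genes made up 19 of 160, 10 of 141, 12 of 174 and 6 of 127 of the calls. With 1 list shifted by 0.5 on the log2 scale and genes drawn independently, camera found it each time and passed 0, 1 and 1 of 25 other lists.

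No pair of libraries of a group agreed within sampling noise (chi-square per degree of freedom 5.83 or more over genes with 20 or more counts in a pair). Same-numbered libraries of fbf-2 and WT deviated from their group means together (correlations 0.521, 0.367 and 0.329 across genes), which meets the rule set for pairing, so blocked values stand beside that comparison; in the other comparisons they did not. Floors of 3 counts and counting intervals cover counting error only. Alternatives were RLE and upper-quartile scaling, other count filters, DESeq2 1.42.0, limma-voom, the replicate block, leaving out each library, stricter thresholds, leaving out sperm, yolk and mitochondrial or ribosomal RNA genes, and fits over all WT, fbf-2 and 3xlnc libraries.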

Results

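Transcript levels were measured by mRNA sequencing of whole adult Caenorhabditis elegans worms of 5 genotypes, with 3 libraries each and 15 in all. WT was the N2 wild type. The fbf-2 strain was mutant in FBF-2 and the fbf-1 strain in FBF-1, a pair of closely related PUF (Pumilio family) RNA-binding proteins that repress mRNAs in the germline and maintain its stem cells. The strain 3xlnc was mutant in 3 genes for long intervening non-coding RNAs, linc-4, linc-7 and linc-29, and the strain fbf-1 3xlnc joined these to the fbf-1 mutation. Total counts per library were 9068700 to 20659808 in WT, 18359546 to 23946404 in fbf-2, 17321508 to 25666906 in 3xlnc, 21731471 to 38453738 in fbf-1 and 28476560 to 30152040 in fbf-1 3xlnc. WT replicate 1 was the shallowest, had 4.63% of its counts on ribosomal RNA genes against 0.515% and 0.975% in the other WT libraries, and had the lowest correlations with its group. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

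The targeted genes followed the labels. The genes linc-4 (chromosome II, 6268939 to 6269516), linc-7 (chromosome X, 16002599 to 16003728) and linc-29 (chromosome IV, 6354024 to 6357243), all on the plus strand of WBcel235, had 0 counts in all 6 libraries of the 3xlnc and fbf-1 3xlnc groups. Against a floor of 3 counts per group they were at least 66.9-fold, 1040-fold and 44.4-fold lower in 3xlnc than in WT, and at least 75.1-fold, 1080-fold and 43.8-fold lower in fbf-1 3xlnc than in fbf-1. In WT they were at 3.82 ± 3.38, 51.5 ± 22.1 and 2.13 ± 0.812 counts scaled to a common library size (CPM, with SD, n = 3), and in fbf-1 at 2.56 ± 0.212, 37.4 ± 2.12 and 1.48 ± 0.324. The fbf-2 gene (chromosome II, 6088863 to 6091480, minus strand) was at 6.69 ± 0.601 CPM in fbf-2 against 28.7 ± 3.14 in WT, a log2 fold change of -2.24 (SE 0.152, edgeR quasi-likelihood adjusted p = 0.000136). The neighbouring fbf-1 gene (6078263 to 6080843, minus strand) was at 8.11 ± 0.289 CPM in fbf-1 and 8.42 ± 0.157 in fbf-1 3xlnc, against 37.8 ± 2.22 in WT. In fbf-2 worms fbf-1 rose to 71.3 ± 0.765 CPM (log2 0.78, SE 0.111, adjusted p = 0.00322). The 2 fbf genes are similar enough to share some reads, so the residual counts may belong to either. In fbf-2 worms linc-7 was also lower (log2 -0.86, adjusted p = 0.04), where WT replicate 1 held 77.0 CPM against 37.9 and 39.6 in the other WT libraries. This call was lost without WT replicate 3 (adjusted p = 0.0675) and without fbf-2 replicate 1, 2 or 3 (adjusted p = 0.0897, 0.125 and 0.0916).

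**Figure D1:**
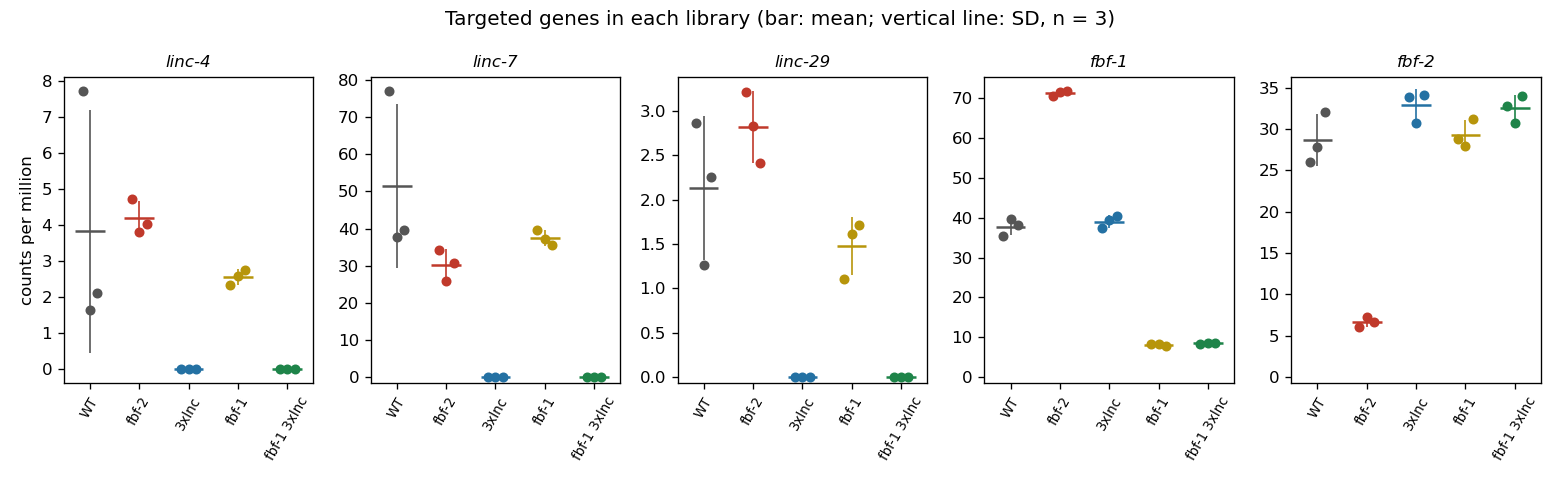
CPM of the 5 targeted genes in each library; points are libraries, horizontal bars means and vertical lines SD (n = 3 per genotype). The 3 linc genes lie at 0 in every 3xlnc and fbf-1 3xlnc library, fbf-2 is at 6.69 CPM in fbf-2 and fbf-1 at 71.3 CPM there.

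Loss of FBF-2 was compared with WT. Large rises included 3 stress genes: the small heat shock genes hsp-16.41 (chromosome V, 1805178 to 1805875) and hsp-16.2 (1804334 to 1804957), and the inducible chaperone gene hsp-70. For hsp-16.41 levels rose from 0.242 ± 0.0772 to 101 ± 26.8 CPM (log2 8.65, SE 0.351, adjusted p = 1.7e-05). For hsp-16.2 they rose from 0.32 ± 0.301 to 83.6 ± 18.5 CPM (log2 8.23, SE 0.373). The change of hsp-70 was 5.29 on the log2 scale. The hsp-16 genes are near-copies that may share reads. F56A4.3 (chromosome V, 2453414 to 2456147) had 0 counts in WT and 22.5 ± 1.24 CPM in fbf-2, at least 374-fold higher. The germline gene fog-3, which promotes sperm fate, rose from 0.56 ± 0.386 to 5.08 ± 0.736 CPM (log2 3.25, SE 0.343, adjusted p = 0.000846). Among genes past the threshold, more fell than rose in the major sperm protein (20 of 28 fell), collagen (28 of 130), innate immunity (47 of 171) and fat lists (33 of 95), none of which passed with an estimated correlation (adjusted p 0.197 to 0.812). Of 13401 genes tested, 738 rose and 1357 fell at an adjusted p under 0.05.

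Among the other large rises were nspe-7 (log2 4.70), Y94H6A.10 (3.18, from 37.2 to 358 CPM) and the non-coding Y71F9AM.9 (3.26). The large falls included C16D9.5 (log2 -4.99), col-43 (-3.74, a collagen gene), H17B01.2 (-3.60), fpn-1.2 (-3.09), and the paired genes pud-3 and pud-4 (-3.20 and -3.05). The major sperm protein gene msp-36 went from 914 counts over the WT libraries to 1, a ratio of normalised counts of 0.00085 (95% counting interval 2.15e-05 to 0.00475). Because major sperm protein genes are near-identical copies, reads may have been split among them.

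Of 28 major sperm protein genes tested, 20 fell, 0 rose and 8 did not pass (22 adjusted over the list alone, camera adjusted p = 4.46e-09, and adjusted p = 0.572 with an estimated correlation). Of 51 spermatogenesis genes 11 fell and 1 rose (17 adjusted over the list alone, adjusted p = 0.000857, and adjusted p = 0.572 with an estimated correlation). Its leading members hil-3 (log2 -1.18) and hil-2 (-0.75) encode linker histones, and nspd-4 (-1.23) a nematode-specific peptide. The meiotic chromosome list was higher on balance (4 of 38 rose, 0 fell; 3 adjusted over the list alone, adjusted p = 3.14e-05, and adjusted p = 0.146 with an estimated correlation). Among its members were spo-11, the enzyme that makes meiotic double-strand breaks, at log2 0.52, and zim-2 at 0.41. The calls of spo-11 and zim-2 were lost without any fbf-2 library or WT replicate 3 (adjusted p 0.0577 to 0.0912), and that of spo-11 also without WT replicate 2 (adjusted p = 0.0607). The heat shock list had 7 of 22 members up and 0 down (9 adjusted over the list alone, adjusted p = 3.2e-06, and adjusted p = 0.197 with an estimated correlation). Of 25 histone genes 5 rose and 1, the linker histone his-24 (log2 -1.45), fell (8 adjusted over the list alone, adjusted p = 0.000682, and adjusted p = 0.639 with an estimated correlation).

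Of 130 collagen and cuticle genes 28 fell and 1 rose (30 adjusted over the list alone, adjusted p = 0.000857, and adjusted p = 0.812 with an estimated correlation), with col-135 at log2 -1.27. Of 70 molting genes 17 fell and 1 rose (27 adjusted over the list alone, adjusted p = 0.000682, and adjusted p = 0.572 with an estimated correlation), led by the cuticle matrix genes noah-1 (-1.64) and noah-2 (-1.32). Of 171 innate immunity genes 47 fell and 6 rose (70 adjusted over the list alone, adjusted p = 0.000165, and adjusted p = 0.572 with an estimated correlation), led by the C-type lectin genes clec-67 (-1.89), clec-186 (-1.42) and clec-223 (-2.17). Of 95 fat metabolism genes 33 fell and 5 rose (40 adjusted over the list alone, adjusted p = 0.000188, and adjusted p = 0.197 with an estimated correlation), led by the lysosomal lipase gene lipl-1 (-2.63) and the acyl-CoA oxidase gene acox-1.2 (-1.72). Of 22 intestine markers 11 fell and 2 rose (15 adjusted over the list alone, adjusted p = 0.00221, and adjusted p = 0.197 with an estimated correlation). Its members included cpr-6 at log2 -0.88, the gut esterase gene ges-1 at -0.77 and the fatty acid desaturase gene fat-5 at 1.11. The early embryo list had 8 down and 1 up of 44 (12 adjusted over the list alone, adjusted p = 0.000459, and adjusted p = 0.572 with an estimated correlation). The yolk list had 1 down of 6 (3 adjusted over the list alone, adjusted p = 0.0242, and adjusted p = 0.772 with an estimated correlation). The muscle list had 1 down of 28 (1 adjusted over the list alone, adjusted p = 0.0139, and adjusted p = 0.778 with an estimated correlation). The somatic gonad list had 4 down of 20 (6 adjusted over the list alone, adjusted p = 0.00558, and adjusted p = 0.772 with an estimated correlation). In these lists the yolk gene vit-1 (-1.00, from 10670 to 5868 CPM) and the muscle gene tni-3 (-0.42) lost their calls without any of 5 single libraries (adjusted p 0.0663 to 0.123). The FBF target list did not pass (3 up, 1 down of 28; 6 adjusted over the list alone, median log2 -0.01, mean 0.09, adjusted p = 0.188). Nor did the stem cell list (1 up, 1 down of 31, with 2 adjusted over the list alone, adjusted p = 0.436). The sex determination list did not pass (3 up, 2 down of 19, with 6 adjusted over the list alone, adjusted p = 0.558), with the calpain gene tra-3 at log2 -0.97. Nor did the oocyte and eggshell list pass (2 up, 3 down of 34; 5 adjusted over the list alone, adjusted p = 0.309). The lists not named here did not pass either, except that ribosomal proteins, with 0 of 79 past the threshold, did under upper-quartile scaling (adjusted p = 0.0427 against 0.11). Of genes the authors' deposited table flags as FBF-2-bound, 103 rose and 31 fell of 1848 tested (median log2 0.05, adjusted p = 6.26e-05, and adjusted p = 0.205 with an estimated correlation), but under upper-quartile scaling 51 rose, 55 fell and the median was -0.02. Of its germline-enriched genes 227 rose and 98 fell of 2558 (adjusted p = 0.00634 with an estimated correlation), against 115 and 129 under upper-quartile scaling. The samples behind these flags are not given in the sources used here, so they may not be independent of these libraries.

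The sample titles state no pairing, and same-numbered libraries of this comparison were taken as paired from their correlations alone. With the number as a block 2073 genes rose and 2340 fell. There were then 20 meiotic, 10 histone, 10 FBF target and 16 innate immunity genes up, and 19 spermatogenesis, 16 early embryo, 73 innate immunity, 26 molting, 13 muscle, 12 somatic gonad, 3 yolk and 3 FBF target genes down. The FBF-2-bound flag had 405 up and 130 down and the germline-enriched flag 699 and 216. Without WT replicate 1 the counts were 2523 and 2480, with 17 meiotic, 11 heat shock and 12 histone genes up, 43 collagen, 27 molting, 19 muscle, 13 somatic gonad and 6 yolk genes down, and 10 FBF targets up and 8 down. In that run 25 innate immunity genes rose, 6 sex determination and 6 oocyte genes fell, 3 stem cell genes rose and 3 fell, and the FBF-2-bound and germline-enriched flags had 462 and 780 up and 259 and 271 down. Upper-quartile scaling, which moved the median of all genes from -0.0373 to -0.114 on the log2 scale, gave 449 and 1682, with 2 meiotic and 3 histone genes up and 3 yolk genes down. RLE scaling gave 7 meiotic, 6 FBF target and 161 FBF-2-bound genes up.

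**Figure D2:**
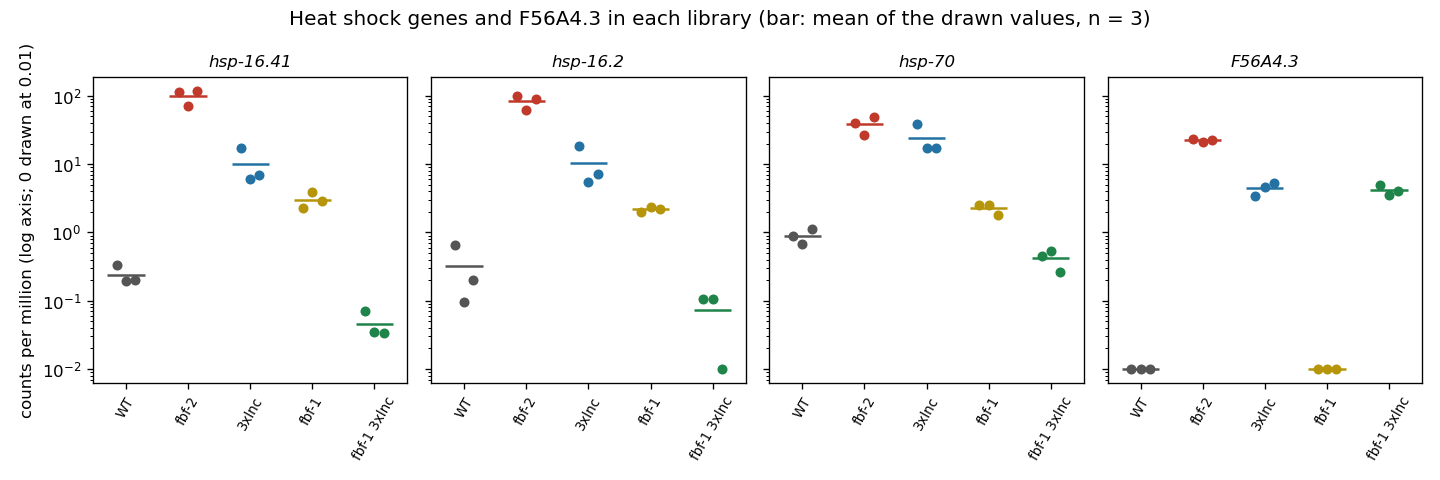
CPM, on a log axis, of hsp-16.41, hsp-16.2, hsp-70 and F56A4.3 in each library (3 per genotype; bars are means of the drawn values, and 0 is drawn at 0.01). The fbf-2 libraries lie at 70.1 to 117 CPM for hsp-16.41, and F56A4.3 has 0 counts in all WT and fbf-1 libraries.

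Loss of the 3 linc genes was compared with WT. Of 133 collagen genes 75 rose, and of 28 major sperm protein genes 25 rose, though neither list passed with an estimated correlation (adjusted p = 0.493 for each). F13H8.8, on the opposite strand 856 bp from linc-4 (chromosome II, 6265609 to 6268083), rose from 1.68 ± 0.192 to 36.3 ± 2.01 CPM (log2 4.37, SE 0.155, adjusted p = 1.92e-06). The heat shock genes hsp-16.41, hsp-16.2 and hsp-70 rose by 5.39, 5.29 and 4.73 on the log2 scale, with 3xlnc levels of 9.96 ± 6.08, 10.3 ± 6.98 and 24.4 ± 12.5 CPM. F56A4.3 again stood at 0 in WT and at 4.44 ± 0.908 CPM in the mutant, at least 75.4-fold higher. Of 13861 genes tested 1304 rose and 292 fell.

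Other large rises included C09B9.7 (log2 3.70), Y102A5C.36 (3.41), R08F11.7 (3.32), the immune gene pals-32 (3.16), and the dehydrogenase gene dhs-26 (2.20). The large falls, apart from those of the mutated linc genes, included pcp-4 (log2 -3.87, from 16.9 ± 3.42 to 1.19 ± 0.136 CPM), the manganese superoxide dismutase gene sod-3 (-3.55), C16D9.5 (-3.17), T05A12.4 (-1.92), Y48E1B.8 (-1.69) and F09C8.1 (-1.55).

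Of 133 collagen and cuticle genes 75 rose and 3 fell (93 adjusted over the list alone, median log2 1.40; adjusted p = 7.53e-15, and adjusted p = 0.493 with an estimated correlation). They included col-135, from 47.3 ± 4.15 to 144 ± 22.3 CPM, col-48 (log2 2.00) and col-147 (2.51). Of 28 major sperm protein genes 25 rose and 0 fell (27 adjusted over the list alone, adjusted p = 5.04e-11, and adjusted p = 0.493 with an estimated correlation), with msp-36 at 0.99 and msp-142 at 1.03. Their summed level was 430 to 600 CPM against 226 to 338 CPM in WT. Of 55 spermatogenesis genes 31 rose and 1 fell (40 adjusted over the list alone, adjusted p = 2.42e-08, and adjusted p = 0.493 with an estimated correlation), with the sperm-specific ssq-3 at 1.43 and ssq-4 at 1.04. Of 181 innate immunity genes 37 rose and 10 fell (64 adjusted over the list alone, adjusted p = 0.000139, and adjusted p = 0.493 with an estimated correlation), led by dod-22 (2.20) and dod-24 (1.09). Of 28 muscle genes 8 rose and 0 fell (20 adjusted over the list alone, adjusted p = 3.2e-07, and adjusted p = 0.493 with an estimated correlation), led by the troponin gene tni-3 (0.59). The detoxification list had 25 up and 5 down of 157 (37 adjusted over the list alone, adjusted p = 0.0109, and adjusted p = 0.522 with an estimated correlation). The heat shock list had 6 up and 1 down of 23 (8 adjusted over the list alone, adjusted p = 0.00106, and adjusted p = 0.493 with an estimated correlation). In the somatic gonad list 1 of 20 rose, tnt-4 by 0.87 on the log2 scale (1 adjusted over the list alone, adjusted p = 0.0139, and adjusted p = 0.62 with an estimated correlation).

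In the stem cell and mitotic zone list 4 of 31 fell and 0 rose (11 adjusted over the list alone, median log2 -0.28; adjusted p = 6.8e-07, and adjusted p = 0.493 with an estimated correlation), including the stem cell gene lst-1 (-0.39) and cdk-1 (-0.37). In the FBF target list 2 fell and 1 rose of 28 (3 adjusted over the list alone, adjusted p = 0.00109, and adjusted p = 0.493 with an estimated correlation), with fog-3 at 2.43 and puf-8 at -0.34. The oocyte and eggshell list had 4 of 34 down (6 adjusted over the list alone, adjusted p = 1.39e-07, and adjusted p = 0.493 with an estimated correlation), including egg-3 (-0.34). The early embryo list had 8 down and 1 up of 45 (9 adjusted over the list alone, adjusted p = 1.36e-07, and adjusted p = 0.493 with an estimated correlation). The meiotic list had 2 of 38 down (0 adjusted over the list alone, adjusted p = 4.26e-07, and adjusted p = 0.0891 with an estimated correlation). Also lower on balance was the PUF family, with 1 down of 11 (4 adjusted over the list alone, adjusted p = 0.0389, and adjusted p = 0.579 with an estimated correlation). The sex determination list had 1 up and 1 down of 19 (1 adjusted over the list alone, adjusted p = 0.0191, and adjusted p = 0.493 with an estimated correlation). The germ granule list had 2 down of 31 (0 adjusted over the list alone, adjusted p = 7.6e-05, and adjusted p = 0.493 with an estimated correlation). Ribosomal protein genes were lower by the test with 1 up of 79 and 0 down (0 adjusted over the list alone, median -0.10, adjusted p = 0.0139, and adjusted p = 0.664 with an estimated correlation). Under upper-quartile scaling the ribosomal and PUF family calls were lost (adjusted p = 0.0512 and 0.0666). The stem cell, FBF target, meiotic, germ granule, sex determination and PUF family lists then had 0 genes down and the oocyte list 1, though all but the PUF family still passed by the preset correlation, and 13 muscle and 14 molting genes rose. The linc family list had 4 of 25 down, the 3 mutated linc genes among them, and did not pass (adjusted p = 0.092, and 0.0227 under upper-quartile scaling), nor did the molting list (7 of 72 up, adjusted p = 0.0554, and 0.049 under RLE scaling). Of genes the authors' deposited table flags as FBF-2-bound, 79 fell and 11 rose of 1847 (adjusted p = 0.0324 with an estimated correlation), against 25 and 23 under upper-quartile scaling. Of its germline-enriched genes 376 rose and 117 fell of 2696, lower by the test (adjusted p = 0.0324 with an estimated correlation) and by the median (log2 -0.17) but not by the mean (0.12). Under upper-quartile scaling 432 of them rose and 32 fell, and with a replicate block 295 and 39.

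Without WT replicate 1, 2439 genes rose and 2325 fell, with 28 stem cell, 31 oocyte, 18 FBF target, 19 meiotic, 25 germ granule and 909 FBF-2-bound genes down and 78 innate immunity, 43 detoxification and 19 muscle genes up. In that run 6 PUF family and 13 sex determination genes fell and 20 molting genes rose, and the germline-enriched flag had 504 up and 1004 down, turning the balance of its calls. The yolk (median log2 -0.32, 0 genes up and 0 down) and neuron lists (14 up, 4 down) then passed with the preset correlation (camera adjusted p = 0.0123 and 0.011). With a correlation estimated over all libraries neither passed (camera adjusted p = 0.93 and 0.664), and none was estimated in that run. The somatic gonad and ribosomal calls were then lost (adjusted p = 0.177 and 0.398). The calls of lst-1, cdk-1, puf-8 and egg-3 were each lost without any of the 5 other libraries (adjusted p 0.0506 to 0.196), and upper-quartile scaling gave 1765 genes up and 145 down.

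**Figure D3:**
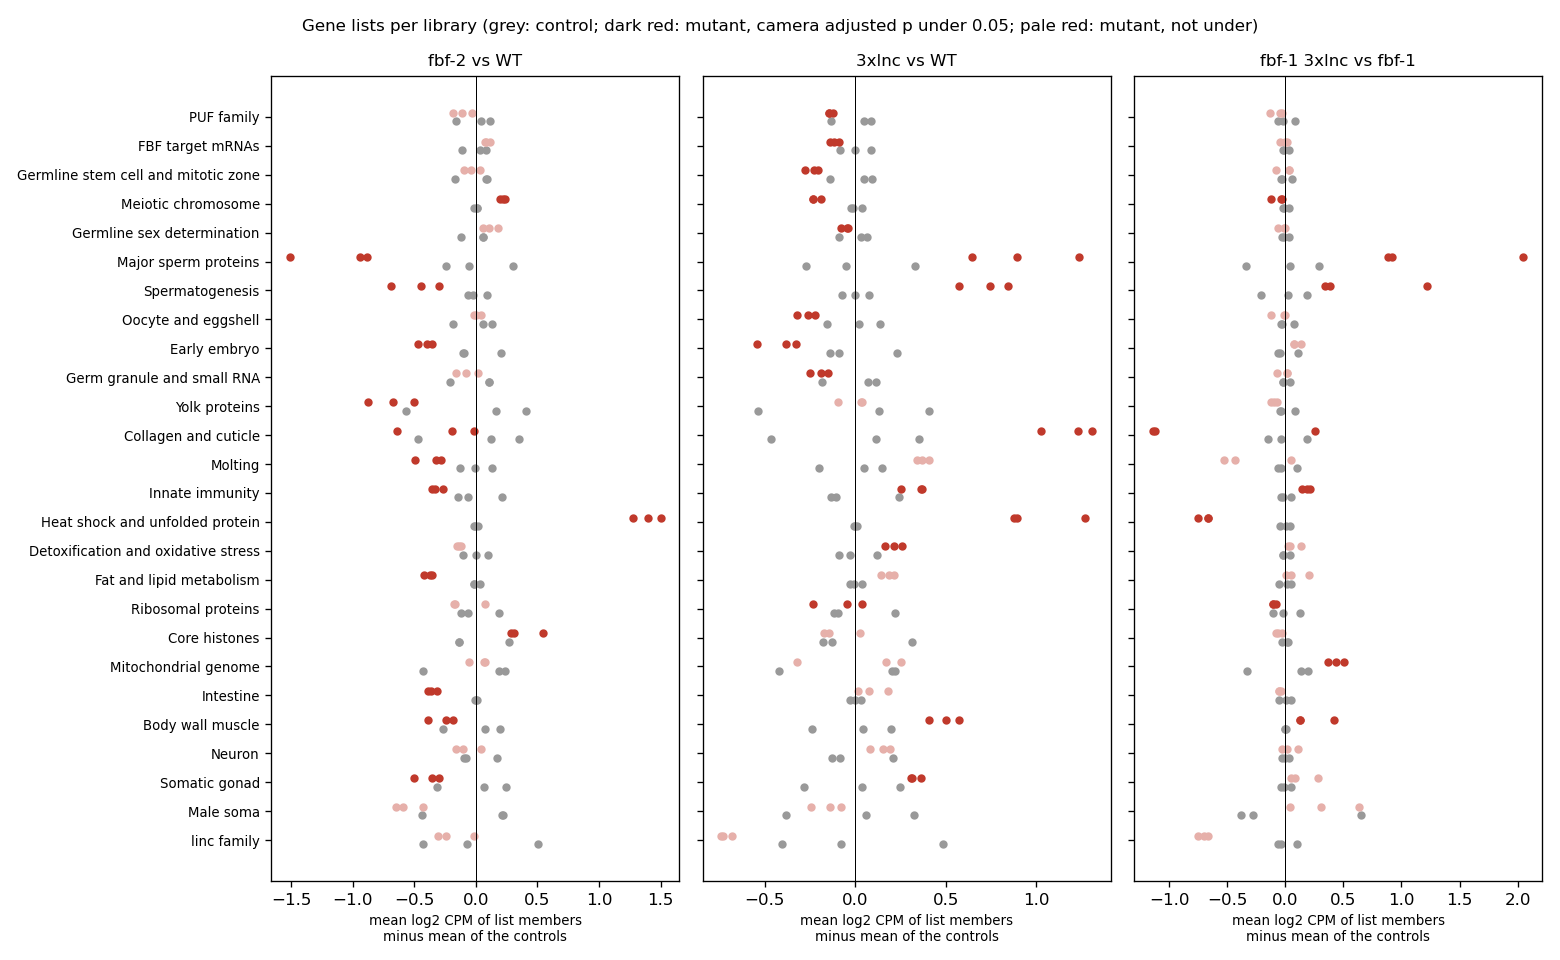
Mean log2 CPM of the tested members of each fixed gene list in each library, minus the mean of the 3 control libraries, for the 3 comparisons. Grey points are control libraries and red points mutant libraries, dark where the preset-correlation camera test passed, and in 3xlnc the collagen list lies at 1.31, 1.03 and 1.23 and in fbf-1 3xlnc at 0.258, -1.14 and -1.12.

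The same 3 mutations were compared in the absence of FBF-1. F13H8.8 rose from 2.07 ± 0.264 to 63.7 ± 1.15 CPM (log2 4.95, SE 0.0711, adjusted p = 1.71e-09), and pcp-4 fell from 10.4 ± 0.35 to 0.827 ± 0.134 CPM (log2 -3.63). F56A4.3 had 0 counts in fbf-1 and 4.17 ± 0.724 CPM in fbf-1 3xlnc, at least 120-fold higher. Of 28 major sperm protein genes 27 rose and of 21 heat shock genes 10 fell, though neither list passed with an estimated correlation (adjusted p = 0.772 and 0.559). The gene hsp-16.41 went from 3.02 ± 0.791 to 0.0461 ± 0.0207 CPM (log2 -5.90, SE 0.384). Of 14104 genes tested 1330 rose and 1197 fell.

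Other rises included dod-22 (log2 3.46), C24B5.4 (3.22), the acyltransferase-family gene oac-59 (3.10), B0024.4 (3.95), C09B9.7 (3.10) and the 18S ribosomal RNA copy rrn-1.2 (3.18), and other falls included the metallothionein gene mtl-1 (-2.58), dod-3 (-2.29), Y48G1BL.5 (-2.26), nspe-1 (-2.11), E01G4.6 (-2.31) and pqn-32 (-1.97). Counts on ribosomal RNA genes made up 2.02 to 4.13% of fbf-1 3xlnc libraries and 0.216 to 0.998% of fbf-1 libraries.

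Of 28 major sperm protein genes 27 rose and 0 fell (28 adjusted over the list alone, adjusted p = 1.28e-08, and adjusted p = 0.772 with an estimated correlation), with msp-19 at log2 2.33. Of 57 spermatogenesis genes 15 rose and 0 fell (27 adjusted over the list alone, adjusted p = 0.000294, and adjusted p = 0.772 with an estimated correlation). Of 178 innate immunity genes 41 rose and 16 fell (63 adjusted over the list alone, adjusted p = 0.00598, and adjusted p = 0.2 with an estimated correlation), with dod-24 at 2.25 and the lysozyme gene lys-2 at 0.75. Of 12 mitochondrial genome transcripts 4 rose (8 adjusted over the list alone, adjusted p = 0.00409, and adjusted p = 0.772 with an estimated correlation), nduo-3 by 0.70. Of 28 muscle genes 10 rose (15 adjusted over the list alone, adjusted p = 0.000127, and adjusted p = 0.772 with an estimated correlation), myo-1 by 0.58. In the heat shock list 10 of 21 fell and 1 rose (14 adjusted over the list alone, adjusted p = 3.93e-05, and adjusted p = 0.559 with an estimated correlation), with hsp-17 at -0.86 and hsp-16.2 at -4.89. Of 79 ribosomal protein genes 9 fell and 1 rose (8 adjusted over the list alone, adjusted p = 0.000134, and adjusted p = 0.772 with an estimated correlation). Of 38 meiotic genes 3 fell (3 adjusted over the list alone, adjusted p = 0.044, and adjusted p = 0.772 with an estimated correlation), with syp-1 of the synaptonemal complex at -0.25. The meiotic call was lost under upper-quartile scaling (adjusted p = 0.0817). The collagen list was lower on balance (12 up and 10 down of 134; 18 adjusted over the list alone, median -0.29; adjusted p = 0.0214, and adjusted p = 0.781 with an estimated correlation), with col-179 at 0.81 and col-90 at -1.90. Library 1 of fbf-1 3xlnc, whose correlation with its group was 0.987 where the others had 0.997, held 587 CPM of major sperm protein reads against 249 and 259. Without it 72 collagen, 23 molting and 14 ribosomal protein genes fell and 13 collagen genes rose, the molting list passed (adjusted p = 0.00024 against 0.0954) and the meiotic list and the FBF-2-bound flag did not (adjusted p = 0.35 and 0.278), nor did the germline-enriched flag (adjusted p = 0.278). The median log2 changes of the major sperm protein and spermatogenesis lists were then 0.812 and 0.382, against 1.32 and 0.881 with that library. In that run 27 and 17 of their genes rose and 0 and 1 fell. The FBF target list did not pass (3 up, 2 down of 28; 5 adjusted over the list alone, adjusted p = 0.853), nor did the stem cell list (1 up of 31, with 0 adjusted over the list alone, adjusted p = 0.895). The sex determination list (2 up, 3 down of 19, with 6 adjusted over the list alone, adjusted p = 0.339) held tra-3 at 0.46. The oocyte list (2 down of 34, with 1 adjusted over the list alone, adjusted p = 0.189) held egg-5 at -0.37. Of the FBF-2-bound genes, by the deposited flag, there were 92 up and 229 down of 1850 tested (adjusted p = 0.00427, and adjusted p = 0.487 with an estimated correlation). Of the germline-enriched genes 188 rose and 325 fell of 2682, lower by the test (adjusted p = 0.0203, and adjusted p = 0.415 with an estimated correlation) and by the median (log2 -0.03) but not by the mean (0.17).

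The 2 genotypes carry sample names of different schemes that could mark separate runs, so a run and the linc mutations cannot be told apart here. Leaving out 1 fbf-1 library at a time gave 1140, 1522 and 1427 genes for replicates 1, 2 and 3. The calls of E01G4.6 and pqn-32 were lost when any 1 of these, or fbf-1 3xlnc library 2 or 3, was left out (adjusted p 0.0542 to 0.122).

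The effect of the 3 mutations was compared between the 2 backgrounds in a model over 12 libraries. It differed for 916 of 14772 genes, being more positive with fbf-1 mutated for 375 and more negative for 541. WT and 3xlnc are labelled total RNA and the 2 fbf-1 groups polyA RNA, so a role of the fbf-1 mutation cannot be told apart from one of the RNA type or the set of libraries. The heat shock genes hsp-16.41 and hsp-16.2 differed most among named genes, by -11.25 (SE 0.819) and -10.16 on the log2 scale, followed by hsp-70 (-7.13), and fog-3 differed by -2.81. As hsp-16.41 held few counts in WT and in fbf-1 3xlnc, the size of its difference is uncertain. The collagen list differed by a median of -1.45 (42 members lower, 3 higher of 140; adjusted p = 1.49e-14, and adjusted p = 0.772 with an estimated correlation). The stem cell list differed by 0.29 (adjusted p = 2.27e-05, and adjusted p = 0.883 with an estimated correlation). Calls in the same direction in both backgrounds numbered 328 up and 44 down, against 120 and 25.1 for independent lists, and across 13587 genes, which are not independent replicates, the fold changes had a correlation of 0.326. Many of the 328 were sperm genes, as 25 of 28 major sperm protein genes rose in 3xlnc and 27 of 28 in fbf-1 3xlnc. These near-identical copies move together and may share reads, so the 328 are not as many separate changes. The comparisons share no library. Without WT replicate 1 the effect differed for 2763 genes, and without any of 8 other single libraries for 545 to 599. Among the 44 were the 3 mutated linc genes, pcp-4 and Y48E1B.8.

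**Figure D4:**
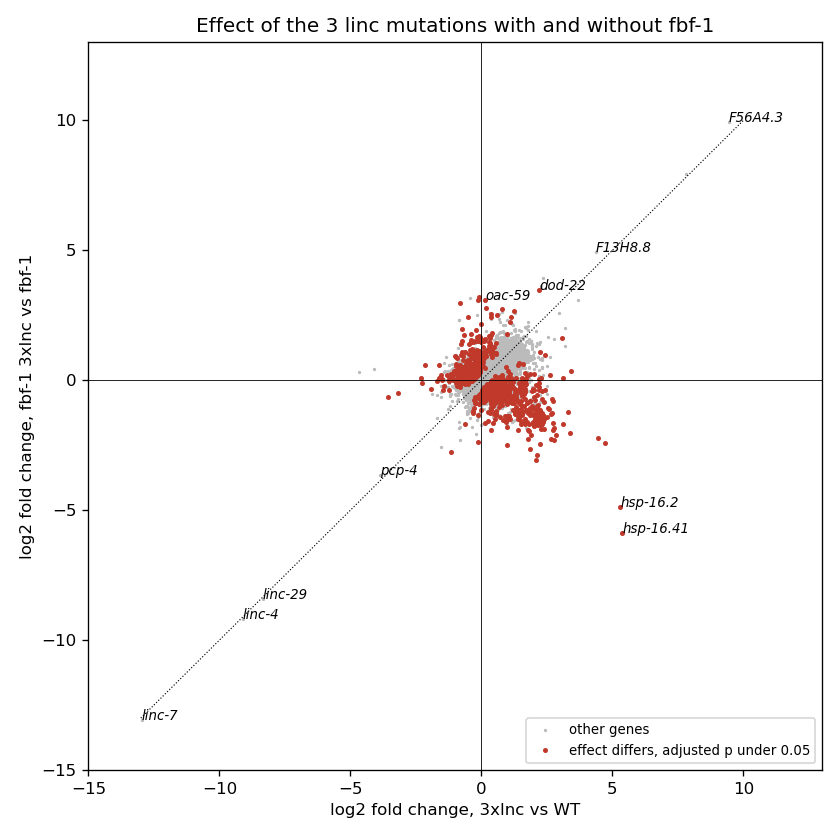
Each point is a gene; the horizontal axis is its log2 fold change in 3xlnc against WT and the vertical axis that in fbf-1 3xlnc against fbf-1, with red for genes whose effect differed (adjusted p under 0.05) and a dotted line of equal change. F13H8.8 and pcp-4 lie near the line, hsp-16.41 and hsp-16.2 far from it; positions of genes at 0 counts in a group are fitted values, not folds.

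The fbf-2 and 3xlnc effects were compared through their common WT libraries. Of genes tested in both, 100 rose and 92 fell in both, against 62.9 and 29.9 for independent lists, and 177 were called in opposite directions, against 136. Across genes, which are not independent replicates, the fold changes had a correlation of 0.132 and a covariance of 0.0421. In 20 simulations of unchanged groups against those controls the means were 0.55 and 0.0299, and the highest covariance was 0.0315. The simulations gave WT the same spread per gene as the other groups and no pairing by number. Real WT libraries varied more (correlations 0.977 to 0.991 within WT, 0.991 to 0.994 within fbf-2 and 0.992 to 0.995 within 3xlnc). The simulated covariance may therefore be too low to set against 0.0421. Part or all of the overlap may come from the shared controls, which with 3 libraries could not be split. Between the fbf-2 effect and that of fbf-1 3xlnc against fbf-1, which share no library, 720 genes were called in opposite directions, against 195 for independent lists (correlation across genes -0.315, genes not being independent replicates), and the 2 pairs also differ in the RNA label.

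**Figure D5:**
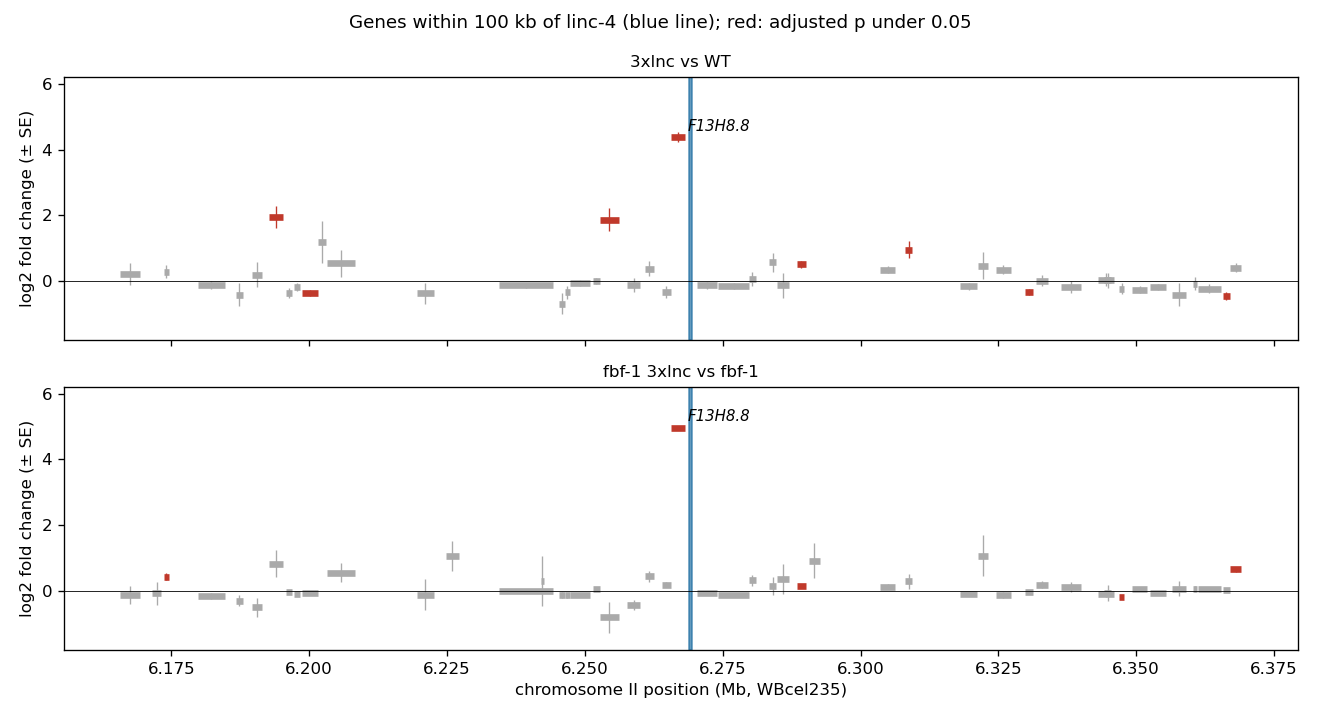
Log2 fold change (with SE) of the tested genes within 100 kb of linc-4 on chromosome II, drawn at their positions in WBcel235; red marks an adjusted p under 0.05 and the blue line linc-4. F13H8.8 stands at 4.37 in 3xlnc and 4.95 in fbf-1 3xlnc, and the other genes shown lie below 2.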

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

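The tests of explanations in this part, other than the counts over splits, were chosen after the results were seen. Groups of 3 libraries were not screened for outlying values. The effect of the 3 linc mutations differed between the backgrounds for 916 genes. Relabelling libraries within both pairs gave as many in 1 of 100 arrangements, the real one, with 202 the highest of the others. Relabelling also mixes each pair's own mutant effect into the spread between libraries, and no arrangement exchanged all labels of a pair. The real labels could then rank first whether or not the effects differ, so the relabelling cannot decide it. The backgrounds also differ in the RNA label (total RNA without the fbf-1 mutation, polyA RNA with it) and in the set of libraries, so whether the difference comes from FBF-1 stays open. Each difference given next is the log2 change in fbf-1 3xlnc against fbf-1 minus that in 3xlnc against WT, and 33 of 105 named genes differed (adjusted p 4.82e-06 to 0.0318).

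More negative with fbf-1 mutated were hsp-16.41 (-11.25), hsp-16.2 (-10.16), hsp-70 (-7.13), E01G4.6 (-5.07), Y48G1BL.5 (-4.91), R08F11.7 (-4.55), nspe-1 (-3.998), pqn-32 (-3.78), dhs-26 (-3.32), col-48 (-3.10), Y102A5C.36 (-3.04), sdz-6 (-3.01), fog-3 (-2.81), cut-2 (-2.79), col-90 (-2.25), hsp-17 (-2.02), col-135 (-1.57), msra-1 (-1.32) and tni-3 (-0.57). More positive were C24B5.4 (3.33), oac-59 (2.98), sod-3 (2.94), C16D9.5 (2.68), T05A12.4 (1.61), dod-22 (1.27), dod-24 (1.16), prg-2 (0.88), sdz-28 (0.87), tra-3 (0.80), cav-1 (0.77), hil-2 (0.71), vet-2 (0.65) and egg-3 (0.43). Among lists, by median difference, were early embryo (0.601), stem cell (0.286), oocyte (0.257), FBF target (0.198), meiotic (0.175), germ granule (0.161), molting (-0.212), muscle (-0.235), heat shock (-0.351) and collagen (-1.45), together with the authors' FBF-2-bound (0.15) and germline-enriched (0.131) flags. With an estimated correlation only the germline-enriched flag passed (adjusted p = 0.0413).

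Of 133 collagen genes 75, and of 28 major sperm protein genes 25, were higher in 3xlnc than in WT, with adjusted p = 0.493 for each list with an estimated correlation. A lower share of germline RNA would raise all somatic lists alike, and the collagen list rose by 0.699 more (log2) than the nearest of the muscle, neuron and intestine lists, 2.17 times the spread of that difference between libraries, which argues against it as the whole cause; sperm genes are themselves germline genes. A younger stage at harvest stays open. The yolk list differed by -0.00838 with a spread of 0.35. WT replicate 1 had 5.50% of its counts on yolk genes against 9.72% and 8.49%, so leaving it out must lower the change of the yolk list. Its median was then -0.322, with 0 genes up and 0 down. The camera adjusted p of 0.0123 used the preset correlation of 0.01, where the one estimated over all libraries was 0.995. A younger stage would give this direction too, so the run without WT replicate 1 cannot decide it. An effect of the linc mutations stays open as well, and so does a difference between cultures, which the design cannot separate.

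The genes hsp-16.41, hsp-16.2 and hsp-70 were higher in fbf-2 and 3xlnc than in WT, while 15 of 22 and 16 of 23 heat shock genes did not pass and the list was lost with an estimated correlation (adjusted p = 0.197 and 0.493). The depth or ribosomal RNA of WT replicate 1 is not the cause, since without it the smaller change of hsp-16.41 was still 5.50 (log2) and past the threshold. A heat exposure of the animals cannot be told apart from the genotypes: the median of 6 cytosolic chaperones (hsp-1, hsp-90, hsp-110, dnj-12, dnj-13 and sti-1) was 0.125 in fbf-2 and 0.11 in 3xlnc, each about 1.04 times the spread between libraries, between what was set for and against it. Handling differences between cultures may therefore contribute, and each genotype was seen in 1 set of 3 libraries. In fbf-1 3xlnc against fbf-1, where hsp-16.41 was lower, the same median was -0.211 with a spread between libraries of 0.0272. There too a difference in heat exposure cannot be told apart from the genotypes.

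F13H8.8 was higher in both 3xlnc comparisons. Reads of linc-4 counted under F13H8.8 would have gone down with linc-4, and F13H8.8 rose by 4.37 (log2) in the comparison with the smaller change, with linc-4 at 0 counts. A wider effect near the 3 loci stays open: of genes within 100 kb, 18.7% passed against 11.4% of others in 3xlnc (Fisher's exact test, two-sided, p = 0.0453), and 9.57% against 18% in fbf-1 3xlnc (p = 0.031), in opposite directions. A local effect of the linc-4 mutation on F13H8.8 itself is a hypothesis that these tables do not test.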

How the results depend on the processing

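The runs without ribosomal RNA genes, the exchanged block numbers and the list counts without single doubted libraries were chosen after seeing the data. Named genes were run under RLE scaling, DESeq2, the replicate block and leaving out each library. No named gene that passed in the main or the alternative run turned its direction there, and genes past in neither were not checked. The balance of some counts did turn. Counts in fbf-2 against WT were 1353 up and 1331 down by DESeq2 and 2523 and 2480 without WT replicate 1 (738 and 1357 as reported). The differing effect was more positive for 1570 genes and more negative for 1193 without WT replicate 1 (375 and 541). In fbf-1 3xlnc against fbf-1, 1356 genes rose and 1364 fell without fbf-1 3xlnc library 1 (1330 and 1197). The median of the FBF-2-bound flag in fbf-2 turned to -0.0223 under upper-quartile scaling. The count of genes in fbf-2 against WT (2095) was 4413 with the replicate block, 693 with an absolute log2 fold change above 1, 639 at an adjusted p under 0.01 and 3432 with all 9 libraries in the fit; without 1 library it was 698 to 5003, with every library moving it over 1.5 times (5003 without WT replicate 1, 1120 and 698 without WT replicates 2 and 3, 789, 837 and 960 without fbf-2 replicates 1, 2 and 3). The count in 3xlnc against WT (1596) was 861 and 407 under the same 2 thresholds and 1109 with the replicate block, and 395 to 4764 without 1 library (4764 without WT replicate 1, 440 without WT replicate 3, 395, 1040 and 432 without 3xlnc replicates 1, 2 and 3). The count in fbf-1 3xlnc against fbf-1 (2527) was 504 and 888 under those thresholds, 2752 with the replicate block and 989 with the block after exchanging numbers 1 and 3, and 1140 to 2720 without 1 library. Same-numbered libraries did not meet the pairing rule in these 2 comparisons (correlations 0.0297, 0.18 and -0.103, then 0.0521, -0.314 and 0.358). The causes were not tested.

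Fewer lists passed with an estimated correlation (0 in each comparison, where 14, 17 and 9 passed) or by fry (9, 7 and 5); without 1 library they were 12 to 14, 15 to 18 and 8 to 10. The splits of the 6 libraries into 3 and 3, 10 each with the real one included, are too few for a share under 0.05. The real gene counts of 2095, 1596 and 2527 were the highest (1 split each, the real one), against 0 in every other split. Every other split puts mutant and control libraries in the same group, which adds any difference between them to the spread within groups. The real gene counts could then rank first in any case, so the 0 counts decide nothing. The real list counts of 14, 17 and 9 were reached by 6, 1 and 6 splits, the real one included, the highest others being 18, 16 and 14. A list call alone therefore does not part genotypes from other differences between libraries. The differing-effect count (916) was 831 with the replicate block and 545 to 2763 without 1 library (2763 without WT replicate 1), and the shared fbf-2 and 3xlnc calls (192) were 55 at an adjusted p under 0.01. DESeq2 gave 1269 up and 545 down in 3xlnc. Folds of 1.5 were often missed at this depth and number of libraries. The alternative on normalised values was not run because the files hold counts.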

Other observations

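Several genes not named by the rule passed in the same direction in both linc-mutant comparisons. They were chosen after their values were seen. The chemoreceptor-family gene srbc-15 had 0 counts in WT and fbf-1 and 1.44 ± 0.151 and 1.06 ± 0.108 CPM in 3xlnc and fbf-1 3xlnc. The genes argk-1 (log2 3.17 and 2.00), lron-14 (2.97 and 2.58) and plep-1 (3.09 and 1.63) were higher in 3xlnc and in fbf-1 3xlnc against their controls, and lys-6 (-1.26 and -1.12) and irg-5 (-0.95 and -0.80), both members of the innate immunity list, were lower in both.

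Counts on the fbf-1 gene were higher in the fbf-2 mutant than in WT (71.3 against 37.8 CPM). The paralogs may share reads, but fbf-2 counts fell in that mutant. Reads of fbf-2 counted under fbf-1 would thus have lowered the fbf-1 counts, which argues against them as the source of the rise. The fbf-2 gene was at 29.4 ± 1.71 CPM in fbf-1 worms and 28.7 ± 3.14 in WT. These values come from libraries that carry different RNA labels and were not tested against each other. In 6 cytosolic chaperone genes the median change in fbf-1 3xlnc against fbf-1 was -0.211 on the log2 scale, with a spread between libraries of 0.0272; sti-1 was at -0.31 (adjusted p = 0.00192) there and at 0.56 (adjusted p = 0.00749) in fbf-2 against WT by edgeR.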
